A study of Homo sapiens with 8 samples.

How the data were processed

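RNA-seq was available for 8 libraries of AML-OCI3, a human acute myeloid leukaemia cell line, treated with DMSO (the vehicle) or with 40 nM JIB-04 (an inhibitor of Jumonji histone lysine demethylases) for 24 h or 48 h, with 2 libraries in each of the 4 groups. Per the labels' protocols, RNA was isolated with TRIzol and poly(A) mRNA libraries were made with a stranded Illumina kit. Nothing in the labels says whether the replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

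The authors deposited 1 table for each time point, and each table gives every library an expected count per gene, as RSEM estimates it, per the file headers. The tables also hold TPM values that the authors computed per library, per the file headers, and these were not used in any test. The authors' deposited tables further give their own comparison of JIB-04 with DMSO at each time, as a log2 fold change, a p-value and an adjusted p-value per gene, per the file headers. They also mark genes as up or down, 299 and 135 at 24 h and 1207 and 607 at 48 h. The largest unadjusted p among the marked genes was 0.0499 at each time. Counts from these tables given below use their adjusted p instead. Cutadapt, STAR 2.6.1, RSEM and the genome build hg38 are named in the submitters' processing notes. The tool behind the authors' own comparison, whether counting used the strand, and the versions of cutadapt and RSEM are not given in the sources used here.

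The expected counts were rounded to whole numbers. The table for 24 h held 27083 genes and that for 48 h held 26805. The 24077 genes present in both were used, of 29811 in either table, and the genes left out carried 0.00581% of all counts. All 29811 Ensembl identifiers were in GENCODE 29, whose hg38 coordinates are given, and 29551 had a symbol in the gene name table used. At each time 24 symbols had been turned into dates, so names were taken from the identifiers. Every per-library column could be assigned to a sample from its name. Library totals lay between 18783093 and 22193377 counts, so that 1 count corresponded to 0.0451 to 0.0532 CPM. CPM values were computed with TMM-scaled library sizes and are given as mean ± SD of 2 libraries.

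Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 15248 genes. All 8 libraries were fitted together in edgeR 4.0.16 under R 4.3.3 with TMM scaling and 1 mean per group, leaving 4 residual degrees of freedom, and edgeR's quasi-likelihood F test was applied to 4 contrasts: JIB-04 against DMSO at 24 h, the same at 48 h, the difference between these 2 effects, and DMSO at 48 h against 24 h. Tests were two-sided. P-values were adjusted by Benjamini and Hochberg over all tested genes, and a gene passed at an adjusted p under 0.05. Log2 fold changes are given ± SE from this fit, and adjusted p-values of genes are from this test unless another tool is named.

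Gene lists were fixed with the tests, the named-gene rule and the main alternatives before the data were examined. The 34 pathway lists covered ferroptosis suppressors, ferroptosis drivers, iron uptake and storage, heme and iron-sulfur cluster biogenesis, NRF2 targets, glutathione metabolism, the ATF4 integrated stress response, the unfolded protein response, p53 targets, the BCL2 family, JmjC histone demethylases, histone methyltransferases with LSD demethylases, hypoxia targets, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, fatty acid metabolism, lysosome, autophagy, G1/S and replication, G2/M and mitosis, replication-dependent histones, MYC and ribosome biogenesis, ribosomal proteins, DNA repair, HOX/MEIS stemness genes, myeloid differentiation, interferon response, NF-κB inflammatory genes, antigen presentation, heat shock, metallothioneins with zinc transporters, and immediate early genes. The 6 lists of other cell types held markers of erythroid, megakaryocyte, T or NK, B or plasma, epithelial and fibroblast cells. The list named after JmjC histone demethylases also held JmjC proteins that are not histone demethylases, such as JARID2 and HIF1AN. A list needed 5 tested members. Lists were tested against all other genes with camera in limma 3.58.1 (inter-gene correlation 0.01), with adjustment over the 34 lists of a contrast. List p-values below are camera's unless said otherwise. Of the calls at the preset correlation, those on G1/S and replication at 24 h, G1/S and replication in the difference between the effects, and the interferon and G1/S lists in DMSO held with an estimated correlation. Limma's fry, an alternative, tests whether a list's genes move on balance one way and does not compare them with other genes.

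Named genes followed a rule. It took the 8 largest rises and 8 largest falls among passing genes with a symbol, a mean log2 CPM of at least 1 and no overlap between the libraries of the compared groups, up to 4 members with the smallest p of each described list, and 18 genes always reported. For the contrast within DMSO and for the difference between effects, the rule took 4 in each direction without the overlap clause.

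The alternatives fixed beforehand were DESeq2 1.42.0 size factors in the edgeR fit, the DESeq2 Wald test, limma-voom, no filter on low counts, the replicate number as a block, a separate fit for each time, each library left out in turn, a minimum change of 2-fold, camera with an estimated correlation and fry. Chosen after seeing the data were a robust edgeR fit, a crossed pairing at 24 h, and an offset that removes a trend on GC content. For the offset, each gene's deviation from its mean over the 8 libraries was smoothed on transcript GC content by lowess (span 0.3) in each library. It also removes any GC-linked difference between groups, and the fit treats the trend as known without error.

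The tests were tried on simulated counts for the 15248 genes, 200 of them changed at 1 time point. Each setting was simulated once per time point, with the same spread per gene in all groups. The replicates of the real groups differed in spread, so the shares below hold for equal spread only. At 24 h the edgeR test found 54% of 2-fold and 83% of 4-fold changes, and 7.43% of its calls were false. At 48 h the figures were 48%, 85% and 4.32%. Of the calls of DESeq2 in the same counts, 13.6% were false at 24 h and 17.1% at 48 h. With a GC trend simulated these DESeq2 shares were 2.70% and 4.94%. With a GC trend simulated as in the libraries, the GC-offset fit found 73% of 2-fold and 86% of 4-fold changes at 24 h with 10.7% false calls, and 83% and 89% at 48 h with 8.02% false calls. The simulated trend had the form that the offset removes, and the spread was that of the GC-offset fit. Good recovery was thus built in and does not vouch for that fit's calls in the real libraries.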

Results

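Gene expression was measured by RNA-seq in AML-OCI3 cells that received DMSO or 40 nM JIB-04 and were collected at 24 h or 48 h. JIB-04 is a small molecule that inhibits Jumonji-domain (JmjC) histone demethylases. The study asked whether it makes acute myeloid leukaemia cells more sensitive to venetoclax, an inhibitor of BCL2, through ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation. All 8 libraries were labelled with DMSO or JIB-04 alone, so the comparisons concern JIB-04 without venetoclax. In DMSO at 24 h the library totals were 20044296 and 21556709 counts, and with JIB-04 at 24 h they were 21186278 and 19626928. In DMSO at 48 h they were 19569169 and 22193377, and with JIB-04 at 48 h 18783093 and 21807056. Between 21394 and 22176 genes were detected per library. The 10 most abundant genes held 7.64% to 9.31% of the counts, EEF1A1, a translation elongation factor, was the most abundant gene in each library, and mitochondrially encoded genes held 6.18% to 8.01%. At 24 h the mitochondrial share was 7.22% and 6.30% in DMSO and 6.55% and 7.23% with JIB-04. At 48 h it was 6.18% and 6.63% in DMSO and 7.26% and 8.01% with JIB-04.

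The replicates of 3 of the 4 groups differed along the GC content of the genes. Across the tested genes, which are not independent replicates, Spearman's rho between the replicate difference and GC content was -0.661 in DMSO at 24 h, 0.707 with JIB-04 at 24 h and 0.630 with JIB-04 at 48 h, against -0.000886 in DMSO at 48 h. Over 9578 well expressed genes, the SD of the log2 difference between replicates was 0.417, 0.320 and 0.263 in those 3 groups and 0.128 in DMSO at 48 h. Once the trend on GC content had been removed from each library, an adjustment chosen after seeing the data, the SDs were 0.228, 0.157 and 0.154, and 0.124 in DMSO at 48 h. At 48 h the groups differed too among the genes of highest GC content. Their median deviation was -0.240 and -0.129 in the DMSO libraries and 0.379 and 0.00249 in the JIB-04 libraries. Effects at 48 h on GC-rich genes in the main fit may include this difference, whose cause was not tested.

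**Figure D1:**
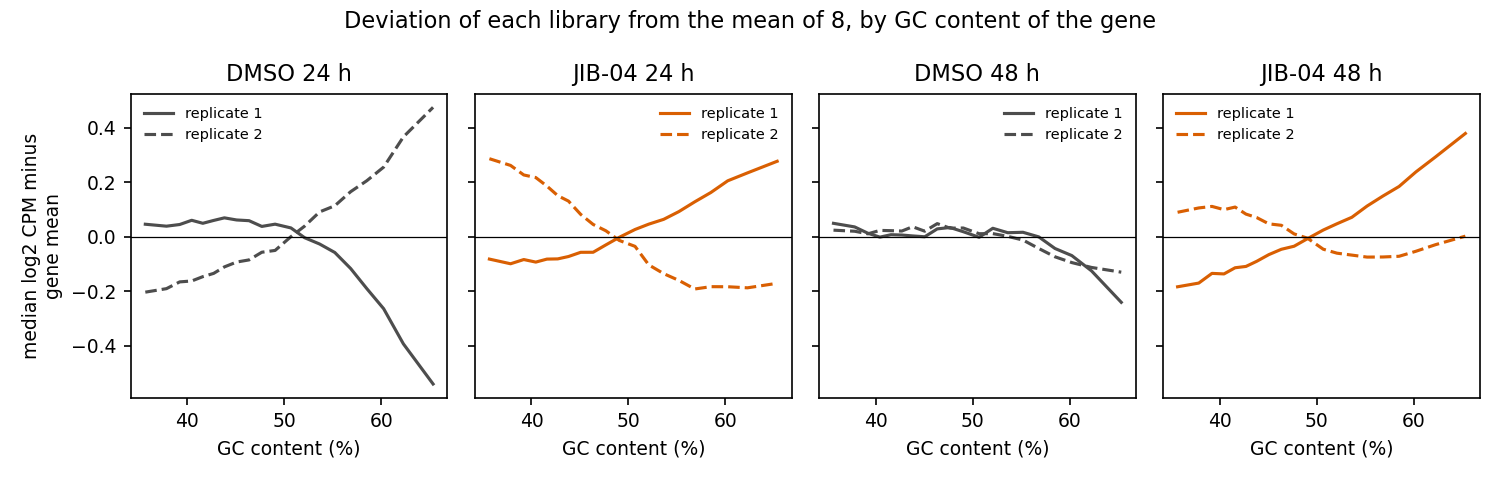
Median log2 CPM minus the gene's mean over the 8 libraries (y axis) in 20 bins of about 762 genes by transcript GC content in percent (x axis), 1 panel per group, with replicate 1 as a solid line and replicate 2 as a dashed line. In the bin of highest GC content the DMSO 24 h replicates lay at -0.54 and 0.47, and the DMSO 48 h replicates at -0.24 and -0.13.

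After 48 h, the genes that rose with JIB-04 included the stress genes GDF15, PPP1R15A and DDIT3 and the ferritin gene FTH1, and those that fell included the cystine importer SLC7A11. GDF15, a secreted stress cytokine, rose by 3.86 ± 0.33 on the log2 scale (SE), from 1.14 ± 0.203 to 16.6 ± 3.76 CPM (SD, n = 2; adjusted p = 0.00373). PPP1R15A, the regulatory subunit that directs dephosphorylation of eIF2α, rose by 2.11 ± 0.16 (24.0 ± 0.331 to 103 ± 12.6 CPM; adjusted p = 0.00302), and DDIT3, which encodes the stress transcription factor CHOP, by 1.49 ± 0.13 (22.0 to 62.1 CPM; adjusted p = 0.00373). FTH1, the ferritin heavy chain that stores iron, rose by 1.20 ± 0.10 (355 ± 14.9 to 813 ± 29.7 CPM; adjusted p = 0.00373). SLC7A11, the cystine importer that feeds glutathione synthesis, fell by 1.06 ± 0.15 (119 ± 0.27 to 56.8 ± 3.73 CPM; adjusted p = 0.0391).

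In all, 59 of 15248 tested genes passed at 48 h, 48 higher and 11 lower, 50 of them by at least 2-fold. Genes with low counts had the highest fitted folds, such as EMP1 (4.31 ± 0.30, 0.290 to 5.85 CPM; adjusted p = 0.00291), chosen after its values were seen, and the naming rule left them out by its minimum of 1 for the mean log2 CPM. Among the genes it named, CEMIP, which is involved in hyaluronan breakdown, rose by 2.86 ± 0.18 (5.22 to 37.9 CPM; adjusted p = 0.00238). ARRDC3, an arrestin-domain protein, rose by 2.38, ZFP36L1, an RNA-binding protein of mRNA decay, by 2.14, CRISPLD2 by 2.21, LRRC25 by 2.0 and RGS2 by 1.98, with adjusted p between 0.00373 and 0.0405. S100P, a calcium-binding protein, fell by 2.17 ± 0.16 (17.9 ± 0.987 to 3.95 ± 0.0971 CPM; adjusted p = 0.00298). VLDLR-AS1 (-1.25), TSC22D3 (-1.0), STC2 (-0.99), PPM1M (-0.98) and the glutamine transporter SLC38A1 (-0.85) also fell, with adjusted p between 0.0431 and 0.0486. PSAT1, an enzyme of serine synthesis, fell by 0.79 ± 0.11 from 652 ± 3.61 to 377 ± 13.5 CPM (adjusted p = 0.0349). VLDLR-AS1 is an antisense gene, and whether counting used the strand is not given in the sources used here, so its count is uncertain.

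The count of 59 moved with each library left out. It was 0 without either DMSO 48 h library, 5 and 8 without JIB-04 48 h replicate 1 and 2, 37 and 36 without JIB-04 24 h replicate 1 and 2, and 109 and 110 without DMSO 24 h replicate 1 and 2. A fit of the 48 h libraries alone called 496 (361 higher, 135 lower), the 59 among them. DESeq2 called 148 genes (105 higher, 43 lower), 57 of the 59 among them, and the authors' deposited table held 438 at an adjusted p under 0.05 (314 higher, 124 lower), 55 of the 59 among them.

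The ferroptosis lists held genes that moved in different directions. Of 24 ferroptosis suppressors, 1 rose (FTH1), 1 fell (SLC7A11) and 22 did not pass, or 2 and 1 adjusted over the list alone, and the list did not differ from other genes (median 0.01; adjusted p = 0.542). GPX4, the peroxidase that removes lipid peroxides, was at 190 ± 14.6 and 197 ± 28.6 CPM (0.05 ± 0.18; adjusted p = 0.954). Of 22 ferroptosis drivers, SAT1, which acetylates polyamines for breakdown, rose by 1.74 ± 0.17 from 13.6 ± 0.0662 to 45.4 ± 1.69 CPM (adjusted p = 0.00701). The other 21 did not pass, and adjusted over the list alone 3 of the 22, SAT1 among them, were higher and 1 lower (list median 0.07; adjusted p = 0.503). ACSL4, which activates polyunsaturated fatty acids, had a log2 change of -0.06 ± 0.16 (adjusted p = 0.931), HMOX1, which degrades heme, 1.17 ± 0.31 (0.241), and CHAC1, which degrades glutathione, -1.16 ± 0.31 (0.250).

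Of 20 genes of iron uptake and storage, FTH1 rose and 19 did not pass, and adjusted over the list alone 3 of the 20, FTH1 among them, were higher and 1 lower (median 0.04; adjusted p = 0.342 with camera, whereas fry called the list higher with an adjusted p = 0.0278). Between the DMSO times, without JIB-04, fry called this list higher too (adjusted p = 0.0356), so such a call is not particular to JIB-04. TFRC, the transferrin receptor, was at 194 ± 5.88 CPM in DMSO and 291 ± 32.7 CPM with JIB-04 (0.59 ± 0.16; adjusted p = 0.250). FTL, the ferritin light chain, had a log2 change of 0.64 ± 0.15 (adjusted p = 0.187), and NCOA4, the receptor that delivers ferritin to lysosomes, 0.09 ± 0.13 (0.857). FTH1 has many processed pseudogenes, so its count may share reads with them. In the authors' deposited table the log2 fold changes at 48 h were 0.58 for TFRC (adjusted p = 5.01e-05), 1.19 for FTH1 (6.73e-30) and -1.07 for SLC7A11 (2.09e-15).

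NRF2 targets, genes of the antioxidant response, were higher than other genes as a list (28 tested, median 0.15; adjusted p = 0.00230, and 0.207 as the adjusted p with an estimated correlation). Of them 5 rose and 1 fell (SLC7A11), or 8 and 1 adjusted over the list alone. Besides FTH1, SQSTM1, an autophagy receptor, rose by 1.65 ± 0.21 (80.9 ± 6.31 to 253 ± 46.9 CPM; adjusted p = 0.0275) and AKR1C1, an aldo-keto reductase, by 1.14 ± 0.14 (18.9 to 41.7 CPM; adjusted p = 0.0211). AKR1C1, AKR1C2 and AKR1C3 are close paralogs between which reads may be split, so their separate values are uncertain.

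The ATF4 integrated stress response list, genes of amino acid supply and stress signalling, was lower as a whole (34 tested, median -0.44; adjusted p = 4.76e-09, and adjusted p = 0.207 with an estimated correlation). The 3 members that rose were GDF15, PPP1R15A and DDIT3, the stress genes above. The 3 that fell were PSAT1, SLC7A11 and STC2, a secreted glycoprotein, and adjusted over the list alone the counts were 3 higher and 22 lower. The unfolded protein response list, chaperones and sensors of the endoplasmic reticulum, was higher (22 tested, median 0.22; adjusted p = 0.00157, and adjusted p = 0.240 with an estimated correlation), with 0 passing by edgeR over all genes and 6 higher adjusted over the list alone. HSPA5, the chaperone BiP, had a log2 change of 0.55 ± 0.11 (adjusted p = 0.125) and DNAJB9, its co-chaperone, 1.25 ± 0.25 (0.119).

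Inflammatory NF-κB genes were higher as a list (25 tested, median 0.53; adjusted p = 1.77e-07, and adjusted p = 0.207 with an estimated correlation). None passed over all genes by edgeR, and 12 were higher and 2 lower adjusted over the list alone. IL1B, an inflammatory cytokine, was at 81.1 ± 0.313 and 130 ± 4.83 CPM (0.68 ± 0.11; adjusted p = 0.0550), whereas the chemokine CCL2 had a log2 change of -0.75 ± 0.14 (0.0914). Immediate early genes were higher too (32 tested, median 0.22; adjusted p = 0.000298, and adjusted p = 0.282 with an estimated correlation). FOS (1.24 ± 0.16; adjusted p = 0.0335), PHLDA1 (1.22 ± 0.17; 0.0349) and the phosphatase DUSP4 (1.20 ± 0.18; 0.0431) rose, 29 did not pass, and 8 of the 32, these 3 among them, were higher adjusted over the list alone.

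Of 19 genes of the BCL2 family, 2 rose and 17 did not pass, the same counts as adjusted over the list alone, and the list did not differ from other genes (median 0.12; adjusted p = 0.262). BCL2L11, which encodes the pro-apoptotic BIM, rose by 0.93 ± 0.12 from 35.9 ± 3.22 to 68.6 ± 0.814 CPM (adjusted p = 0.0335), and BCL2A1, an anti-apoptotic member, by 1.80 ± 0.25 from 4.2 to 14.6 CPM (adjusted p = 0.0353). BCL2, the target of venetoclax, was at 291 ± 12.5 and 238 ± 17.9 CPM (-0.29 ± 0.11; adjusted p = 0.451). The log2 changes were 0.12 for MCL1 (adjusted p = 0.810), 0.20 for BCL2L1 (0.781), 0.07 for BAX (0.949), -0.32 for PMAIP1 (0.534) and 1.03 for BBC3 (0.474). CDKN1A, a p53 target that restrains the cell cycle, had 0.33 (0.583). In the authors' deposited table BBC3 had 1.03 at 48 h (adjusted p = 0.0305). With the GC trend removed, 4 of the 19 family members rose by edgeR at 48 h, BAD, BAK1, BCL2A1 and BCL2L11. BCL2 alone fell, and 14 did not pass, BBC3 among them.

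Among 25 tested genes of the JmjC list, not all of them histone demethylases, 0 passed by edgeR over all genes or adjusted over the list alone (median 0.07; adjusted p = 0.503). KDM4A had a log2 change of -0.19 ± 0.11 (adjusted p = 0.617), KDM5A 0.14 ± 0.14 (0.757), KDM6A 0.14 ± 0.15 (0.786) and KDM7A -0.61 ± 0.16 (0.232). Over all tested genes at 48 h, 1477 had an unadjusted p under 0.05.

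Myeloid differentiation genes were higher as a list at 48 h (32 tested, median 0.29; adjusted p = 0.0102, and adjusted p = 0.265 with an estimated correlation). CD163, a macrophage scavenger receptor, rose by 1.08 ± 0.15 (6.96 to 14.8 CPM; adjusted p = 0.0372), 31 did not pass, and 4 of the 32, CD163 among them, were higher adjusted over the list alone. LYZ, lysozyme, had 0.62 ± 0.12 (adjusted p = 0.0981). The list's call ended once the GC trend was removed (median 0.05; adjusted p = 0.157) and without JIB-04 48 h replicate 1 (adjusted p = 0.121). Interferon response genes were lower (36 tested, median -0.14; adjusted p = 0.00577, and adjusted p = 0.274 with an estimated correlation), with 0 passing by edgeR over all genes or adjusted over the list alone. OAS2 had -0.59 ± 0.13 (adjusted p = 0.152) and IFI6 -0.56 ± 0.15 (0.247). The interferon call was lost without JIB-04 48 h replicate 1 (adjusted p = 0.201) or DMSO 48 h replicate 2 (0.0723).

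**Figure D2:**
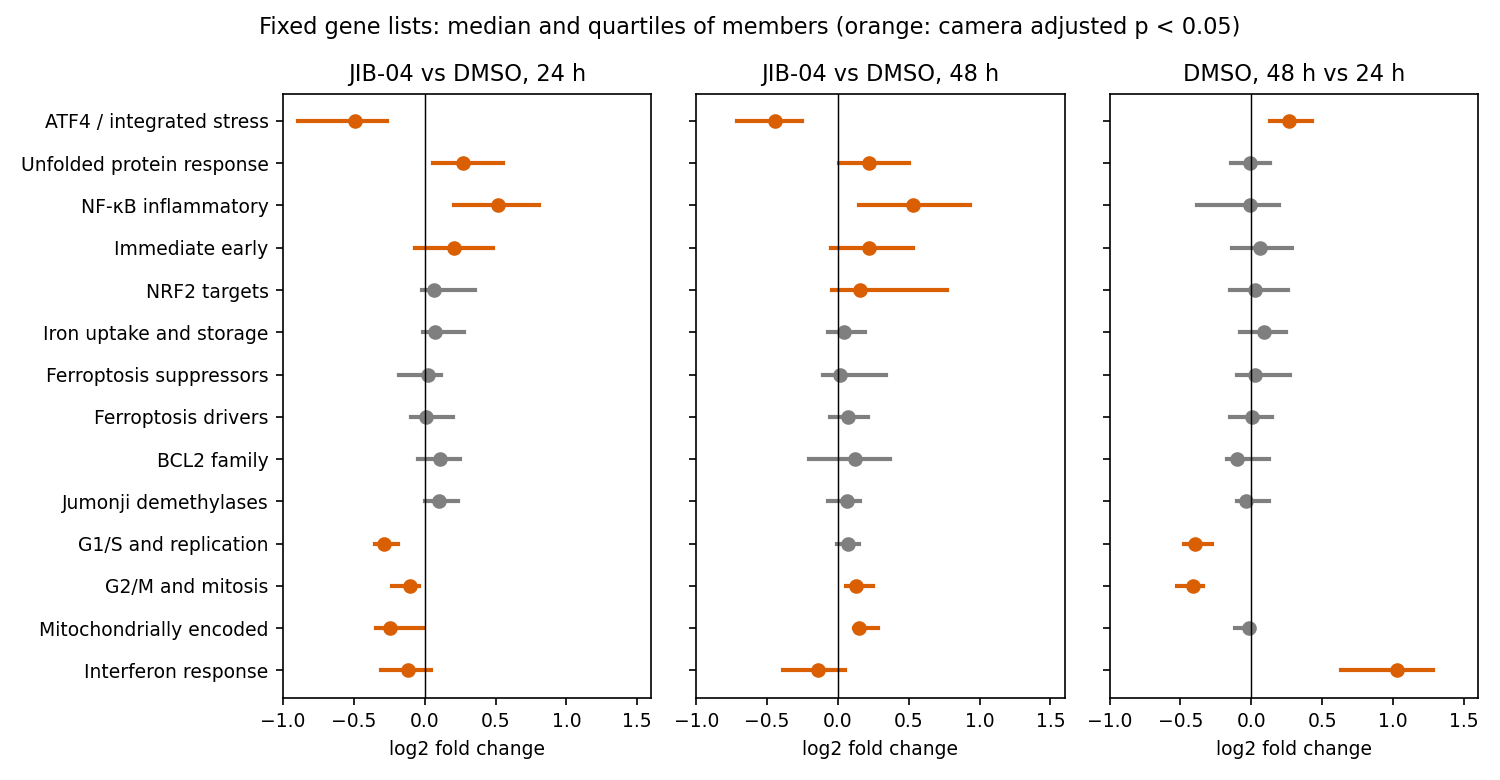
Log2 fold change of the members of 14 fixed gene lists (x axis; point, median; line, quartiles) for JIB-04 against DMSO at 24 h and at 48 h and for DMSO at 48 h against 24 h, with lists at a camera adjusted p under 0.05 in orange. The ATF4 median lay at -0.49 at 24 h and -0.44 at 48 h, and the interferon median at 1.03 between the DMSO times.

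The comparison at 24 h asked what JIB-04 had done a day earlier. No gene passed in edgeR's test, where the smallest adjusted p was 0.0841, while 1647 genes (10.8%) had an unadjusted p under 0.05, 1028 higher and 619 lower. Limma-voom also called 0 genes and DESeq2 91 (58 higher, 33 lower). The count was 36 with no filter on low counts and 1 without DMSO 24 h replicate 1. The authors' deposited table held 23 genes at an adjusted p under 0.05 (14 higher, 9 lower).

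The smallest unadjusted p at 24 h belonged to DNAJB9, PSAT1, S100P and TFRC in that order, and many genes shared their adjusted p of 0.0841. S100P had a log2 change of -1.86 ± 0.22 (0.0841) and CEMIP 1.21 ± 0.17 (0.0841). TFRC was at 203 ± 25.2 CPM in DMSO and 505 ± 94.6 CPM with JIB-04 (1.31 ± 0.16; adjusted p = 0.0841). DNAJB9 had a log2 change of 2.43 ± 0.27 (2.93 ± 0.686 and 15.7 ± 3.06 CPM; 0.0841), HSPA5 0.88 ± 0.12 (451 ± 25.2 and 829 ± 81.5 CPM; 0.0841) and MANF, a secreted factor of endoplasmic reticulum stress, 0.91 ± 0.13 (0.0841). PSAT1 had -0.93 ± 0.11 (539 ± 55.4 and 283 ± 12.1 CPM; 0.0841) and WARS1, a tRNA synthetase, -0.71 ± 0.10 (0.0841). DDIT3 had 0.89 ± 0.13 (0.0841), GDF15 2.33 ± 0.40 (0.123) and PPP1R15A 1.04 (0.0845). In the authors' deposited table the log2 fold changes at 24 h were 1.30 for TFRC (adjusted p = 2.17e-05) and 2.41 for DNAJB9 (adjusted p = 3.47e-07).

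Of 9 lists called at 24 h, the ATF4 list was lower (34 tested, median -0.49; adjusted p = 4.16e-13, and adjusted p = 0.0792 with an estimated correlation), with 3 higher (DDIT3, GDF15, PPP1R15A) and 20 lower adjusted over the list alone and 0 over all genes by edgeR. VLDLR, a lipoprotein receptor, had -0.93 ± 0.14 (adjusted p = 0.0841). G1/S and replication genes were lower (39 tested, 38 of them negative, median -0.29; adjusted p = 2.04e-11), a call kept with an estimated correlation (adjusted p = 0.0382). Of these 6 were lower adjusted over the list alone. MCM3, a subunit of the replicative helicase, was at 400 ± 7.6 and 290 ± 16 CPM (-0.46 ± 0.10; adjusted p = 0.211), and GINS2 had -0.50 ± 0.12 (0.236). G2/M and mitosis genes were lower by less (36 tested, median -0.11; adjusted p = 0.00162, and adjusted p = 0.428 with an estimated correlation), with 0 adjusted over the list alone, a call lost without DMSO 24 h replicate 1 (0.228) or JIB-04 24 h replicate 1 (0.237).

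NF-κB genes were higher at 24 h (25 tested, median 0.51; adjusted p = 4.93e-06, and adjusted p = 0.232 with an estimated correlation), 7 higher and 1 lower (CCL2) adjusted over the list alone. The cytokine TNF was at 29 ± 2.06 and 62.4 ± 9.22 CPM (1.10 ± 0.14; adjusted p = 0.0841), and CCL2 had -1.01 ± 0.14 (0.0841). Unfolded protein response genes were higher (22 tested, median 0.27; adjusted p = 5.15e-06, and adjusted p = 0.232 with an estimated correlation), 6 of them adjusted over the list alone. Immediate early genes were higher (median 0.21; adjusted p = 0.00779, and adjusted p = 0.428 with an estimated correlation), 3 of 32 adjusted over the list alone, among them PHLDA1 (0.96 ± 0.16; adjusted p = 0.123). Lower at 24 h were nuclear-encoded oxidative phosphorylation (43 tested, median -0.10; adjusted p = 0.0115, and adjusted p = 0.353 with an estimated correlation), interferon response (median -0.11; 0.0140, and adjusted p = 0.353 with an estimated correlation) and mitochondrially encoded genes (13 tested, median -0.24; 0.0167, and adjusted p = 0.583 with an estimated correlation). MT-CO3, a subunit of cytochrome c oxidase, had -0.44 ± 0.09 (adjusted p = 0.202) and MX1 -0.47 ± 0.14 (0.309). Adjusted over the list alone, 1 mitochondrially encoded gene was lower and 0 of the other 2 lists by edgeR.

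The immediate early, oxidative phosphorylation, interferon and mitochondrially encoded calls at 24 h were lost without DMSO 24 h replicate 1 (adjusted p = 0.228, 0.228, 0.192 and 0.531) and without JIB-04 24 h replicate 1 (0.184, 0.0878, 0.0878 and 0.330). Without DMSO 24 h replicate 1, 4 lists were called in all.

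Of the ferroptosis genes at 24 h, SLC7A11 was at 90.3 ± 13 and 52.0 ± 8.3 CPM (-0.80 ± 0.15; adjusted p = 0.160), FTH1 at 393 ± 26.0 and 413 ± 4.79 CPM (0.07 ± 0.10; 0.854), and SAT1 had 0.99 ± 0.17 (0.123). CHAC1 had -1.30 ± 0.32 (0.245), HMOX1 0.71 ± 0.31 (0.460), GPX4 -0.16 ± 0.18 (0.823), ACSL4 0.11 ± 0.16 (0.873) and NCOA4 -0.05 ± 0.13 (0.948). None of 24 suppressors passed over all genes by edgeR and 1 was lower adjusted over the list alone (median 0.02, mean -0.04, tested as lower; adjusted p = 0.548). Of 22 drivers, 2 were higher and 1 lower adjusted over the list alone (median 0.01; adjusted p = 0.485), and of 20 iron genes 2 were higher (median 0.07, positive in 14; 0.165). Fry, the other list test, called the iron list higher (adjusted p = 0.00767) but not the suppressors (0.893) or drivers (0.0920). It also called the iron list higher between the DMSO times (adjusted p = 0.0356). In the BCL2 family 1 of 19 was higher adjusted over the list alone (median 0.11; 0.483), with BCL2L11 at 0.54 ± 0.12 (0.219), BCL2 at 0.16 ± 0.11 (0.671), MCL1 at 0.08, BCL2L1 at 0.16, BAX at -0.05, PMAIP1 at 0.04, BBC3 at 0.32 and CDKN1A at -0.02. The JmjC list had a median of 0.10 (25 tested, 0 adjusted over the list alone by edgeR; adjusted p = 0.165), with KDM4A at -0.10, KDM5A at 0.13 and KDM6A at 0.25.

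With the GC trend removed, the alternative chosen after seeing the data, 1612 genes passed at 24 h (905 higher, 707 lower) and 1195 at 48 h (720 higher, 475 lower), all 59 genes called at 48 h among them. This fit gives all groups 1 spread, although the replicate SD stayed at 0.228 in DMSO at 24 h against 0.124 in DMSO at 48 h. Its SEs and calls at 24 h may therefore look too firm. TFRC then rose by 1.21 ± 0.06 at 24 h (adjusted p = 3.97e-05, over a range of 8.76e-10 to 0.708 in 18 alternatives, of which 4 passed), and SLC7A11 fell by 0.99 ± 0.06 at 24 h (adjusted p = 0.00014, over 0.00014 to 0.947, with 3 passing). HSPA5 rose by 0.86 ± 0.06 at 24 h (0.00014, over 2.41e-06 to 0.708, with 4 passing) and TNF by 1.15 ± 0.07 (8.25e-05, over 2.86e-06 to 0.708, with 4 passing). FTH1 at 24 h had 0.09 ± 0.06 in this fit (0.349). Some other named genes passed in this fit but not in the main edgeR fit. At 48 h BCL2 fell by 0.26 ± 0.05 (0.0179, over 0.0179 to 0.999 in 18 alternatives, with 1 passing), CHAC1 by 1.42 ± 0.15 (0.000722, over 0.000441 to 0.998, with 4 passing) and KDM7A by 0.58 ± 0.06 (0.00062, over 0.00062 to 0.998, with 4 passing). HMOX1 rose by 1.05 ± 0.27 (0.0441, over 0.0441 to 0.998, with 1 passing), TFRC by 0.61 ± 0.06 (0.000439, over 0.000439 to 0.998, with 3 passing) and FTL by 0.58 ± 0.06 (0.00086, over 0.00086 to 0.984, with 4 passing). At 24 h CHAC1 fell by 1.32 ± 0.16 (0.0021, over 0.00184 to 0.960, with 3 passing), while SAT1 rose by 0.93 ± 0.10 (0.00164, over 0.00164 to 0.880, with 3 passing) and BCL2L11 by 0.52 ± 0.08 (0.00519, over 0.00519 to 0.960, with 2 passing). DESeq2 without this adjustment gave CHAC1 an adjusted p of 0.00772 at 24 h and 0.0197 at 48 h, and the authors' deposited table gave it -1.17 at 48 h (adjusted p = 8.16e-08).

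With the GC trend removed, the count at 24 h was 944 without DMSO 24 h replicate 1, 621 and 317 without JIB-04 24 h replicate 1 and 2, and 873 and 876 without DMSO 48 h replicate 1 and 2. At 48 h the count was far lower without any single library of that time and somewhat lower without either JIB-04 24 h library. Without either DMSO 24 h library, however, the 48 h count was higher than with all libraries.

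List calls also moved when the GC trend was removed. Camera then called the JmjC list higher at 24 h (median 0.06, 4 rose, 0 fell and 21 did not pass; adjusted p = 0.0119). By edgeR in this fit KDM6B rose by 0.70 ± 0.07 (0.00129), KDM3A by 0.36 ± 0.06 (0.00891), JMJD1C by 0.33 ± 0.07 (0.0176) and JARID2 by 0.25 ± 0.06 (0.0255). In the main fit their adjusted p was 0.357 to 0.463. Camera also called DNA repair genes lower (-0.13; 0.00867) and fatty acid metabolism lower (-0.08; 0.0338) at 24 h, and at 48 h cholesterol synthesis higher (0.11; 0.0478). For the difference between the effects it called cholesterol synthesis (0.18; 0.0140) and DNA repair (0.16; 0.000402) higher and HOX/MEIS stemness genes lower (-0.11; 0.0111), and between the DMSO times hypoxia targets higher (0.11; 0.0323). With an estimated correlation in this fit the adjusted p of these calls was 0.157 to 0.597. The metallothionein call between the DMSO times was lost (0.0877). At 24 h the G2/M median became -0.19 (6.95e-08, 10 of 36 lower) and the interferon median -0.20 (0.00601). At 48 h the immediate early median became 0.12 (0.0139) and the NRF2 median 0.10 (0.00685), and the myeloid median of the difference 0.20 (0.00663). With an estimated correlation these 5 calls were lost, with an adjusted p of 0.0974, 0.410, 0.253, 0.253 and 0.334 in that order, whereas G2/M genes passed for the difference (0.0455) and between the DMSO times (0.0274). These list calls were not refitted without each library.

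Fry, without the GC adjustment, did not call some of the lists that camera called. Its adjusted p at 24 h was 0.288 for G2/M, 0.374 for mitochondrially encoded, 0.224 for interferon and 0.110 for immediate early genes. At 48 h it was 0.0584 for immediate early, 0.0818 for myeloid and 0.0994 for interferon genes, and between the DMSO times 0.112 for ribosomal proteins, 0.557 for DNA repair, 0.223 for antigen presentation and 0.0747 for metallothioneins.

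**Figure D3:**
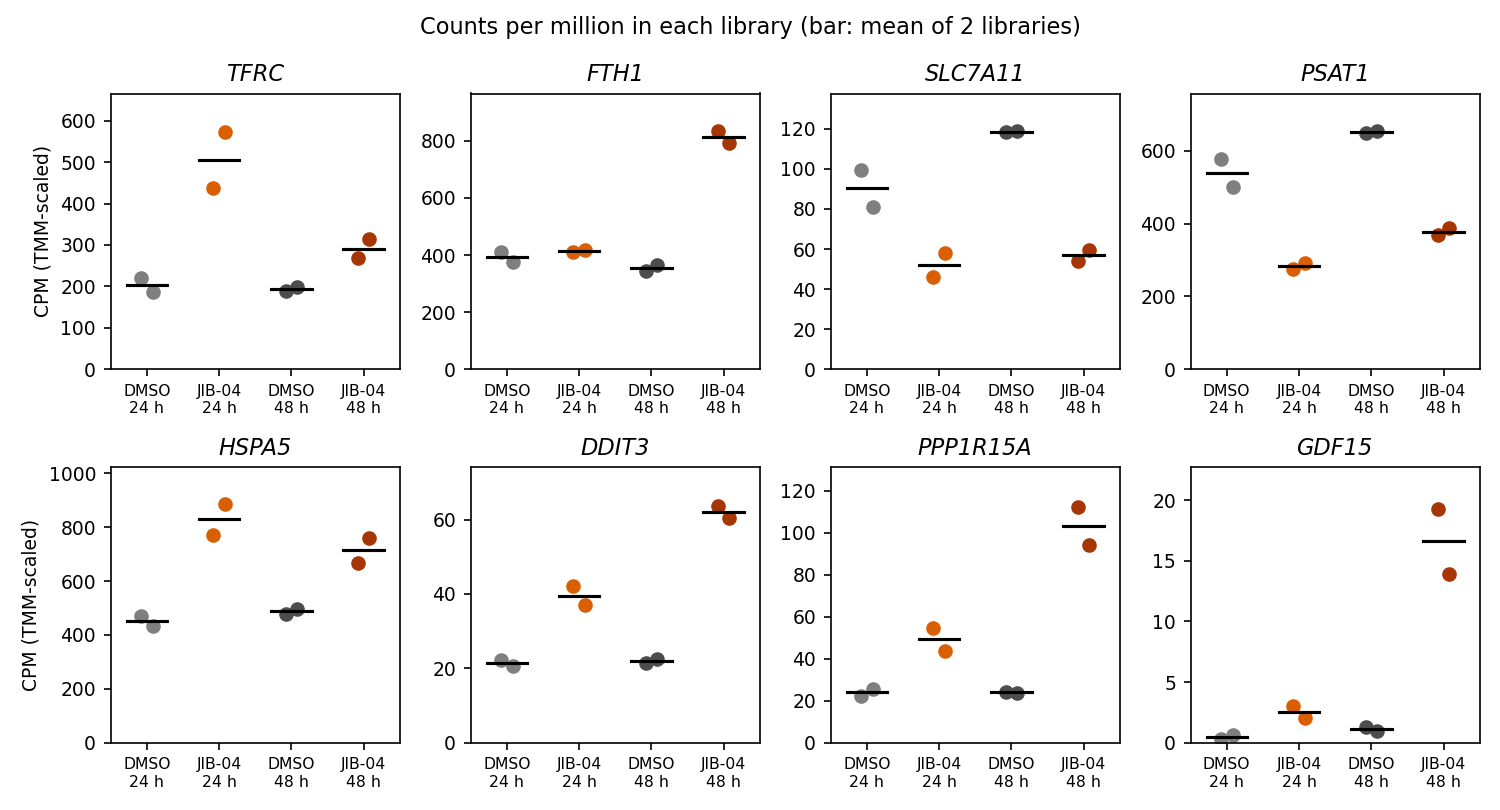
TMM-scaled CPM (y axis, from 0) of TFRC, FTH1, SLC7A11, PSAT1, HSPA5, DDIT3, PPP1R15A and GDF15 in the 4 groups (x axis), with 1 point per library and a bar at the mean of 2. FTH1 averaged 393, 413, 355 and 813 CPM in DMSO 24 h, JIB-04 24 h, DMSO 48 h and JIB-04 48 h, and TFRC 203, 505, 194 and 291 CPM.

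Whether the effect of JIB-04 differed between 24 h and 48 h was tested as the difference of the effects. By edgeR 0 genes passed (smallest adjusted p 0.0842), 798 (5.23%) had an unadjusted p under 0.05, DESeq2 called 12 and limma-voom 1, and without DMSO 48 h replicate 2 edgeR called 1. For FTH1 the 48 h effect exceeded the 24 h effect by 1.12 ± 0.14 (adjusted p = 0.167), and for PPP1R15A by 1.07 ± 0.22 (0.754). For TFRC the difference was -0.73 ± 0.22 (0.931), for DDIT3 0.61 ± 0.18 (0.931) and for SLC7A11 -0.26. With the GC trend removed 169 genes passed (108 higher, 61 lower), and the count was 273 without DMSO 24 h replicate 1, 8 and 6 without JIB-04 24 h replicate 1 and 2, 5 without either DMSO 48 h library, and 5 and 10 without JIB-04 48 h replicate 1 and 2. FTH1 was among the 169 (1.13 ± 0.08; adjusted p = 0.00239, over 2.63e-06 to 1 in 17 alternatives, with 3 passing), as were TFRC (-0.60 ± 0.08; 0.0187, over 0.0187 to 1, with 1 passing) and BCL2 (-0.39 ± 0.08; 0.0451, over 0.0451 to 1, with 1 passing).

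As lists, 5 differed between the times, each with a higher value at 48 h. G1/S and replication genes differed by a median of 0.34, positive in 39 of 39 (adjusted p = 8.07e-11), a call kept with an estimated correlation (adjusted p = 0.0402), with GINS2 at 0.59 ± 0.17 and MCM3 at 0.47 ± 0.14 (each 0.931). G2/M and mitosis genes differed by 0.30 in 35 of 36 (4.03e-07, and adjusted p = 0.359 with an estimated correlation), with MKI67, a proliferation marker, at 0.41 ± 0.15. Mitochondrially encoded genes differed by 0.37 in 13 of 13 (3.95e-06, and adjusted p = 0.466 with an estimated correlation), with MT-ND5 at 0.51 ± 0.17. Oxidative phosphorylation genes differed by 0.17 in 38 of 43 and myeloid differentiation genes by 0.32 in 26 of 32 (0.00185 and 0.00282, each with an adjusted p = 0.359 with an estimated correlation). The oxidative phosphorylation call was lost without DMSO 24 h replicate 1 (adjusted p = 0.133) and the myeloid call without DMSO 24 h replicate 2 (0.0938), while 9 lists were called without JIB-04 24 h replicate 1 or without JIB-04 48 h replicate 2.

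The effects at the 2 times, which were measured against different DMSO libraries, were also compared gene by gene. Of the 59 genes called at 48 h, 54 had the same sign at 24 h, 45 of 48 that rose and 9 of 11 that fell. In 47 of the 59, both JIB-04 libraries at 24 h lay beyond both DMSO libraries in the 48 h direction. The 59 were called in a fit with 1 spread per gene over all groups, which favours genes whose replicates lie close at 24 h. The 16.7% of a random order is therefore not a baseline for them. In a fit of the 24 h libraries alone, 24 of 57 of these genes passed when adjusted over these genes alone, 23 of them with the same sign. The same choice of genes favours this count. With an unadjusted p under 0.05 at both times, 238 genes were higher at both (53.3 would be found between independent lists), 147 lower at both (27.8) and 28 opposite (78.4). Both p-values of a gene share its spread, which raises such overlaps in either sign, so the numbers for independent lists are too low a baseline. Across all tested genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.179 and Spearman's rho 0.243. Pearson's r was 0.0318 and 0.261 without DMSO 24 h replicate 1 and 2, 0.0419 without JIB-04 24 h replicate 1 and 0.101 without DMSO 48 h replicate 1.

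**Figure D4:**
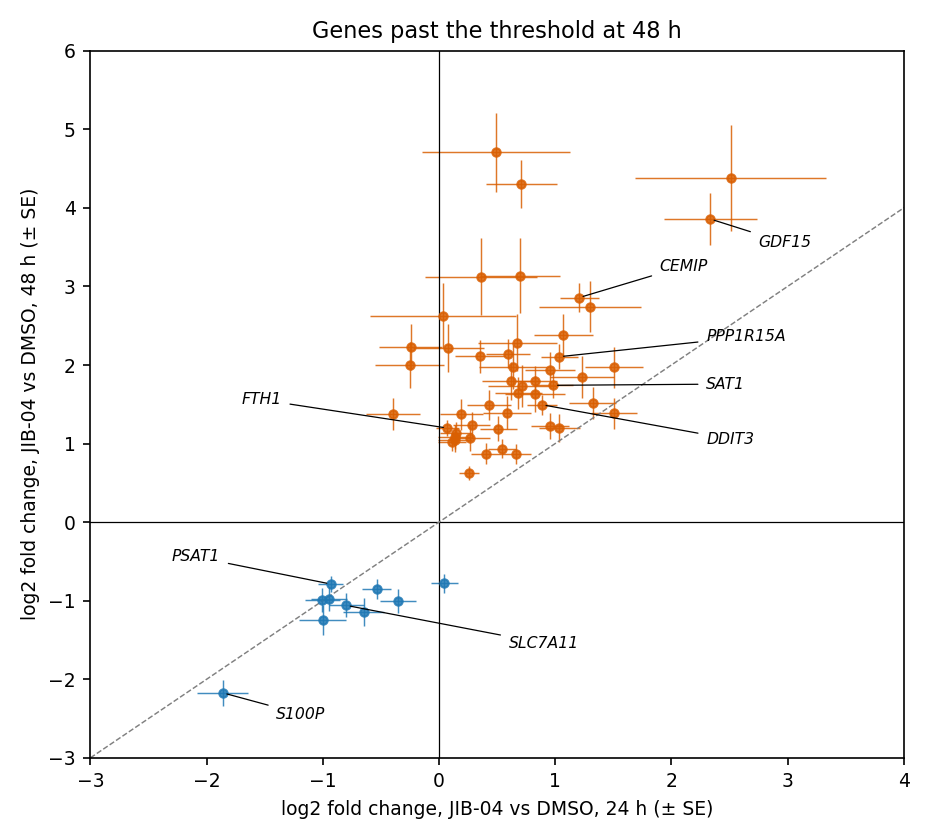
Log2 fold change of JIB-04 against DMSO at 24 h (x axis) and 48 h (y axis), ± SE, for the genes called at 48 h (orange, rose; blue, fell), with the dashed line marking equal effects and AC138696.1 outside the axes. FTH1 lay at 0.07 and 1.20, and GDF15 at 2.33 and 3.86.

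The DMSO cultures at 48 h were compared with those at 24 h to show what differed between the times in the controls. Time goes together with harvest here, so culture time cannot be told apart from a difference between harvests or library batches. Interferon-induced genes rose. MX1, an antiviral GTPase, rose by 1.81 ± 0.13 from 10.3 ± 0.0575 to 36.1 ± 1.67 CPM (adjusted p = 0.00419), IFI44L by 2.6 ± 0.25 from 5.89 to 35.7 CPM (0.0108), and OAS2, an activator of RNase L, by 1.59 ± 0.13 from 50.5 to 152 CPM (0.00765). S100P rose by 2.96 ± 0.17 from 2.29 ± 0.158 to 17.9 ± 0.987 CPM (0.00109). The same DMSO 48 h libraries stand behind its fall with JIB-04 at 48 h, so these S100P values are not independent. The same limit holds for CEMIP, which fell by 1.46 in DMSO (14.4 to 5.22 CPM; 0.0208) and was at 33.2 and 37.9 CPM with JIB-04 at 24 h and 48 h. It holds as well for other genes called in both comparisons, chosen after their values were seen: GZMA, CD163 and ATXN7 (ENSG00000285258) fell in DMSO and were higher with JIB-04 at 48 h, CA2 and AC138696.1 rose in DMSO and were lower with JIB-04, and AKR1C1 rose in both.

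In total 65 genes passed between the DMSO times, 40 higher and 25 lower. IFI44 (2.10 ± 0.21; adjusted p = 0.0108) and the pseudogene OR52K3P (2.20 ± 0.26; 0.0208) were among the genes that rose. ROPN1L (-2.00 ± 0.20; 0.0108), GZMA, a granzyme (-1.95 ± 0.20; 0.0108), NOD2, a sensor of bacterial peptidoglycan (-1.82 ± 0.29; 0.0453), and CDH24 (-1.67 ± 0.27; 0.0491) were among those that fell, and CD163 fell by 1.29 ± 0.15 (0.0188). DESeq2 called 227 (116 higher, 111 lower), and 113 passed with no filter on low counts. The count of 65 was 1 and 2 without DMSO 48 h replicate 1 and 2, 41 and 18 without DMSO 24 h replicate 1 and 2, and 24 and 23 without JIB-04 48 h replicate 1 and 2. With the GC trend removed it was 2065 (1021 higher, 1044 lower), and 504 and 590 without DMSO 48 h replicate 1 and 2.

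Of 36 interferon response genes, 14 rose over all genes and 27 adjusted over the list alone (median 1.03; adjusted p = 9.48e-30, and adjusted p = 0.0231 with an estimated correlation). Cell-cycle lists were lower in DMSO at 48 h. G1/S and replication genes had a median of -0.40 (adjusted p = 1.46e-15, and adjusted p = 0.0213 with an estimated correlation) with 15 of 39 lower adjusted over the list alone, and G2/M and mitosis genes -0.41 (1.95e-16, and adjusted p = 0.179 with an estimated correlation) with 18 of 36. MKI67 had -0.57 ± 0.10 (0.0734) and MCM4 -0.44 ± 0.09 (0.103). The ATF4 list was higher by a median of 0.27 (2.42e-06, and adjusted p = 0.179 with an estimated correlation; 6 of 34 adjusted over the list alone), with asparagine synthetase, ASNS, at 0.70 ± 0.14 (0.0939). Ribosomal protein genes were higher by 0.26 (8.05e-08, and adjusted p = 0.560 with an estimated correlation; 13 of 40 adjusted over the list alone) and antigen presentation genes by 0.29 (0.00273, and adjusted p = 0.588 with an estimated correlation; 1 of 14, HLA-B at 0.62 ± 0.13). DNA repair genes were lower by a median of -0.17 (0.00341, and adjusted p = 0.726 with an estimated correlation), oxidative phosphorylation genes by -0.12 (0.00499, and adjusted p = 0.432 with an estimated correlation) and metallothioneins with zinc transporters by -0.14 (0.0317, and adjusted p = 0.309 with an estimated correlation). The DNA repair, oxidative phosphorylation, antigen presentation and metallothionein calls were lost without DMSO 24 h replicate 1 (adjusted p = 0.587, 0.305, 0.282 and 0.103), and the metallothionein call also without DMSO 48 h replicate 2 (0.0754).

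The main genes lie on hg38 as annotated in GENCODE 29. TFRC (ENSG00000072274) spans 196027183 to 196082189 on chromosome 3, FTH1 (ENSG00000167996) 61959718 to 61967660 on chromosome 11 and SLC7A11 (ENSG00000151012) 138164097 to 138242349 on chromosome 4. GDF15 (ENSG00000130513) lies at 18374731 to 18389176 and PPP1R15A (ENSG00000087074) at 48872392 to 48876057, both on chromosome 19. DDIT3 (ENSG00000175197) spans 57516588 to 57521737 on chromosome 12, PSAT1 (ENSG00000135069) 78297143 to 78330093 and HSPA5 (ENSG00000044574) 125234853 to 125241330 on chromosome 9, and DNAJB9 (ENSG00000128590) 108569568 to 108574850 on chromosome 7. BCL2 (ENSG00000171791) lies at 63123346 to 63320128 on chromosome 18, BCL2L11 (ENSG00000153094) at 111119378 to 111168447 on chromosome 2, S100P (ENSG00000163993) at 6693069 to 6697170 on chromosome 4, CEMIP (ENSG00000103888) at 80779343 to 80951776 on chromosome 15 and MX1 (ENSG00000157601) at 41420304 to 41459214 on chromosome 21.

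Markers of other cell types were low. The highest gene of each list, averaged over the libraries, was TFR2 at 10.6 CPM among erythroid, GP1BA at 2.25 among megakaryocyte, EBF1 at 5.98 among B or plasma cell, MUC1 at 2.19 among epithelial and ACTA2 at 6.28 CPM among fibroblast markers. Of the T or NK cell markers CD4, which monocytic cells also express, reached 234 CPM. The lists had 2, 4, 2, 1, 5 and 3 tested members in that order. The fibroblast list alone had enough members for a test, and its adjusted p was 0.852 at 24 h, 0.802 at 48 h, 0.867 for the difference between times and 0.253 between the DMSO times, with a median of -0.29 and a mean of 0.08 at 48 h. Adjusted over this list alone 1 member was higher and 1 lower at 48 h. Once the GC trend was removed FAP, at 0.216 and 0.821 CPM, rose by 1.93 ± 0.50 (0.0477, over 0.0477 to 0.998 in 18 alternatives, with 1 passing) and TAGLN, at 3.13 and 1.62 CPM, fell by 1.02 ± 0.25 (0.0400, over 0.0400 to 0.998, with 1 passing). IL7R, on the T or NK list, fell by 1.17 ± 0.17 between the DMSO times (adjusted p = 0.0351). With JIB-04 at 48 h IL7R had 0.72 ± 0.17 (0.178) and NKG7, on the same list, 1.10 ± 0.27 (0.206). With the GC trend removed both rose at 48 h, IL7R by 0.74 ± 0.08 (0.00104, over 0.00104 to 0.984 in 18 alternatives, with 3 passing) and NKG7 by 0.98 ± 0.16 (0.00672, over 0.00392 to 0.998, with 5 passing), and IL7R rose at 24 h by 0.52 ± 0.07 (0.00398, over 0.00398 to 0.960, with 2 passing). In the authors' deposited table NKG7 had 1.09 at 48 h (adjusted p = 0.00688) and IL7R 0.72 (0.0199).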

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

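The list tests were fixed beforehand, and the tests of explanations in this part were chosen after the result was seen. Each result stands out because the JIB-04 effect of a gene list at 48 h differed from that at 24 h in the test of the difference itself. For G1/S and replication genes the adjusted p was 8.07e-11 (median difference 0.34, positive in 39 of 39), and for G2/M and mitosis genes 4.03e-07 (0.30, 35 of 36). Mitochondrially encoded genes had 3.95e-06 (0.37, 13 of 13), nuclear-encoded oxidative phosphorylation genes 0.00185 (0.17, 38 of 43) and myeloid differentiation genes 0.00282 (0.32, 26 of 32). With an estimated correlation the G1/S call held (adjusted p = 0.0402), and the other 4 were lost, each with an adjusted p there, in the order above, of 0.359, 0.466, 0.359 and 0.359, the highest over the alternatives. The G2/M call held with an estimated correlation once the GC trend was removed as well (0.0455). The lowest came to 3.16e-15, 1.04e-16, 1.69e-11 and 2.24e-05 for the first 4 lists, with the GC trend removed, and 0.0016 for the myeloid list. With fry the same 4 were lost (0.248, 0.248, 0.128 and 0.248). The oxidative phosphorylation call also ended without DMSO 24 h replicate 1 (0.133) and the myeloid call without DMSO 24 h replicate 2 (0.0938).

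The difference in the G1/S and G2/M lists was weighed further. The trend on GC content between replicates is argued against as its whole cause, since with that trend removed the list medians were at least 1.11 times as large. A single library is argued against too: over the 8 fits without a library, the largest adjusted p of these lists was 0.0136. A fall of cell-cycle genes between the DMSO times, by culture time or harvest, is a candidate explanation. The G1/S median went by -0.40 and the G2/M median by -0.41 from 24 h to 48 h in DMSO against -0.01 and -0.16 with JIB-04. These medians are the parts from which the difference is formed and share its libraries, so they describe the difference without showing why it arose. The same difference can be read as a lower G1/S list with JIB-04 at 24 h (median -0.29) than at 48 h (0.07), and an effect of JIB-04 that itself changes with time stays open and untested.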

How the results depend on the processing

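The GC trend removal, the crossed pairing and the robust fit were chosen after the result was seen, and the other tests were fixed beforehand. No called list changed direction, and no named gene changed sign where it passed in either fit. Changes of sign did occur among genes that passed in neither, such as GPX4 at 48 h (0.05, and -0.22 with the GC trend removed), ACSL4 at 24 h (0.11 and -0.06) and BAX at 48 h (0.07 and -0.08), and in the median of the uncalled JmjC list at 48 h (0.07 and -0.02). No alternative fixed beforehand was left unrun. Counts are given in the order 24 h, 48 h, difference between the effects, and DMSO over time, against 0, 59, 0 and 65 genes. DESeq2 called 91, 148, 12 and 227 genes. With no filter on low counts the numbers were 36, 87, 1 and 113, with the GC trend removed 1612, 1195, 169 and 2065, and limma-voom called 1 for the difference. Fits made for each time alone called 0 at 24 h and 496 at 48 h (361 higher, 135 lower). DESeq2 size factors in the edgeR fit and the robust fit moved no count by over 1.5 times. Without each library in turn the counts were 0 to 1, 0 to 110, 0 to 1 and 1 to 59 (by library: 24 h, 1 without DMSO 24 h replicate 1; difference, 1 without DMSO 48 h replicate 2; 48 h, as given in the report; DMSO over time, 41 and 18 without DMSO 24 h replicate 1 and 2, 1 and 2 without DMSO 48 h replicate 1 and 2, 24 and 23 without JIB-04 48 h replicate 1 and 2), where a group left with 1 library was assumed to vary like the other groups. The cause was not tested. Leaving out a library leaves fewer samples, which alone is no reason for the higher 48 h count without either DMSO 24 h library. The fit gives each gene 1 spread over all groups, so the kept libraries of every group enter it. The replicate SD was 0.417 in DMSO at 24 h and 0.128 in DMSO at 48 h.

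Of the gene lists 9, 12, 5 and 9 were called in the same order. With an estimated correlation the counts were 1, 0, 1 and 2, and fry called 7 at 48 h and 1 for the difference. The difference had 8 lists with the GC trend removed and 8 with the crossed pairing. Without each library in turn the lists numbered 4 to 10, 7 to 13, 5 to 9 and 5 to 9 (4 and 5 without DMSO 24 h replicate 1 at 24 h and over time, 7 without JIB-04 48 h replicate 1 at 48 h, 9 without JIB-04 24 h replicate 1 or JIB-04 48 h replicate 2 for the difference). Pearson's r between the effects at both times, 0.179, was 0.0462 with no filter and 0.0318 to 0.261 without a library (0.0318 and 0.261 without DMSO 24 h replicate 1 and 2, 0.0419 without JIB-04 24 h replicate 1, 0.101 without DMSO 48 h replicate 1, 0.114 without DMSO 48 h replicate 2, 0.113 without JIB-04 48 h replicate 1). The cause of these shifts was not tested. Over all named genes and their alternatives, 9936 values kept their side of the threshold, 637 newly passed it, 265 no longer did and 94 changed sign without passing. Of the values of called lists 569 kept their side and 82 no longer passed. In counts simulated at this depth without a GC trend, edgeR found 54% of 2-fold changes at 24 h and 48% at 48 h, and 52% at each time with the trend simulated. Apart from that trend every group was simulated with the same spread, whereas the replicate SD was 0.417 in DMSO at 24 h and 0.128 in DMSO at 48 h. These shares thus do not give the power of the test at either time.

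With the replicate number as a block over all libraries the counts of genes were 0, 8, 0 and 2, and with a block within each time 0, 0, 0 and 0. The labels give the numbers no shared origin. The block test rests on replicate differences that go together within a number, whose correlation over all genes was -0.363 for DMSO and JIB-04 at 24 h (-0.766 over 9578 expressed genes, -0.386 of these with the GC trend removed) and -0.00132 at 48 h. It was 0.331 between JIB-04 at 24 h and at 48 h (0.820, and 0.391 with the GC trend removed). Numbers crossed between the groups at 24 h are therefore left open. A crossed pairing at 24 h gave 305, 396, 5 and 672 genes.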

Other observations

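The tests of explanations in this part were chosen after the result was seen, while the list tests were fixed beforehand. Further lists and genes at 48 h follow. Among metallothioneins and zinc transporters, which bind and move zinc and copper, 5 of 15 were higher and 1 lower adjusted over the list alone (median 0.23; adjusted p = 0.0217, and adjusted p = 0.240 with an estimated correlation). MT2A was at 6.80 ± 0.597 CPM in DMSO and 33.3 ± 10.4 CPM with JIB-04 (2.29 ± 0.42; adjusted p = 0.0873, and 7.01e-07 to 0.726 over the alternatives) and MT1X had 1.58 ± 0.28 (0.0779, and 5.93e-06 to 0.661). How reads shared between metallothionein paralogs were counted was not tested. The zinc exporter SLC30A1 had 0.96 ± 0.18 at 24 h (0.160, and 0.00241 to 0.924 over the alternatives). Lysosomal genes were higher (33 tested, median 0.08; adjusted p = 0.0247, and adjusted p = 0.240 with an estimated correlation), and the protease CTSL rose by 1.07 ± 0.17 (19.2 to 40.4 CPM; 0.0486). Of 32 autophagy genes SQSTM1 and WIPI1 rose, WIPI1 by 1.49 ± 0.19 (0.0286), and 4 were higher adjusted over the list alone (the list was not called, adjusted p = 0.0960). PLIN2, a coat protein of lipid droplets, rose by 1.02 ± 0.12 (98.3 to 199.9 CPM; 0.0211) and was the only one of 32 fatty acid genes to pass over all genes, a list that was not called.

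Also higher as lists at 48 h were p53 targets (34 tested, median 0.15; adjusted p = 0.0218, and adjusted p = 0.240 with an estimated correlation), of which GDF15 rose over all genes, G2/M and mitosis genes (median 0.13; 0.00961, and adjusted p = 0.493 with an estimated correlation) and mitochondrially encoded genes (median 0.15; 0.0108, and adjusted p = 0.586 with an estimated correlation), 2 of which, MT-ND4 at 0.54 ± 0.11 and MT-ND4L at 0.57 ± 0.11, were higher adjusted over the list alone. Leaving out 1 library ended several of these calls. Without JIB-04 48 h replicate 1, 7 of the 12 lists called at 48 h were left, and the adjusted p was 0.101 for metallothioneins, 0.147 for lysosomal genes and 0.0808 for p53 targets. Without DMSO 48 h replicate 2 it was 0.0656, 0.102 and 0.0620 in that order. The mitochondrial call ended without DMSO 48 h replicate 1 (0.144) or JIB-04 48 h replicate 2 (0.245), and the G2/M call without JIB-04 48 h replicate 2 (0.116). The metallothionein call also ended with the GC trend removed (0.0714), with fry (0.0584) and with the 48 h libraries fitted alone (0.0516). Fry also ended the G2/M (0.219) and mitochondrial (0.237) calls. Over the alternatives the adjusted p was 0.00994 to 0.240 for metallothioneins, 0.0211 to 0.240 for lysosomal genes, 0.0149 to 0.240 for p53 targets, 5.34e-06 to 0.493 for G2/M and 7.46e-05 to 0.586 for mitochondrially encoded genes.

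The other lists were not called by camera in the main fit. Some alternatives without the GC adjustment called more lists, such as 10 against 9 at 24 h with limma-voom and 13 against 12 at 48 h with no filter on low counts. Their adjusted p at 24 h and 48 h was 0.701 and 0.345 for heme and iron-sulfur cluster genes (at 24 h median -0.01, mean 0.01, tested as lower), 0.257 and 0.514 for glutathione metabolism, 0.165 and 0.542 for histone methyltransferases with LSD demethylases, 0.548 and 0.503 for hypoxia targets, and 0.155 and 0.456 for glycolysis. It was 0.512 and 0.0794 for cholesterol synthesis, 0.147 and 0.668 for fatty acid metabolism (at 48 h median -0.02, mean 0.04, tested as lower), 0.701 and 0.0962 for replication-dependent histones (at 24 h median 0.03, mean -0.07, tested as lower), and 0.499 and 0.423 for MYC and ribosome biogenesis. For ribosomal proteins it was 0.0522 and 0.835 (at 48 h median 0.01, mean 0.03, tested as lower), for DNA repair 0.221 and 0.802, for HOX/MEIS stemness genes 0.483 and 0.133, for antigen presentation 0.939 and 0.139, and for heat shock 0.548 and 0.503. At 24 h alone it was 0.165 for NRF2 targets, p53 targets and autophagy, 0.489 for lysosome, 0.608 for myeloid differentiation and 0.296 for metallothioneins, and at 48 h alone 0.277 for oxidative phosphorylation and 0.406 for G1/S and replication. Besides the iron list, fry called some lists at 24 h that camera did not: NRF2 targets (adjusted p = 0.0495), p53 targets (0.0449), autophagy (0.0449) and histone methyltransferases with LSD demethylases (0.0426) as higher, and fatty acid metabolism (0.0184) as lower.

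AC138696.1 (ENSG00000264668), chosen after its values were seen, went in opposite directions at the 2 times. It had 0 CPM in both DMSO 24 h libraries and 1.89 ± 0.266 CPM with JIB-04 at 24 h, against 1.64 ± 0.519 CPM in DMSO and 0.0272 ± 0.0385 CPM with JIB-04 at 48 h (SD, n = 2). The adjusted p was 0.0841 at 24 h, 0.0398 at 48 h and 0.0842 for the difference between the effects. No fold is given because it would rest on groups with hardly any counts, and no explanation was tested.

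That no gene passed at 24 h by edgeR was weighed against the spread between libraries; 1647 genes had an unadjusted p under 0.05, DESeq2 called 91 and limma-voom 0. A swap of a DMSO and a JIB-04 library at 24 h is argued against: over the genes called at 48 h, the lowest JIB-04 score exceeded the highest DMSO score by 0.554, where replicates differed by at most 0.0449. The call of these genes favours close replicates at 24 h, so the 0.0449 may understate the spread. The trend on GC content may account for much of the spread, since the SD of replicate differences went to 0.548 of its value or less in both 24 h groups once it was removed. A response smaller than that at 48 h and one of like size cannot be told apart. With the trend removed the count at 24 h was 1.35 times that at 48 h. That fit gives all groups 1 spread per gene, with a median SE of 0.112 at each time. The replicate SDs still differed, 0.228 and 0.157 in DMSO and JIB-04 at 24 h against 0.124 and 0.154 at 48 h. Calls may thus come too readily at 24 h and too rarely at 48 h. Leaving out a library of one time also lowers the count of that time by construction, so these counts do not decide.

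The lower ATF4 list under JIB-04 was the other pattern followed up. The GC trend is argued against as its whole cause, since the list medians kept at least 0.970 of their size without it. A rise of ATF4 targets in DMSO between the times is argued against as the whole cause, because the list was lower at 24 h already (median -0.49), a call that camera lost with an estimated correlation (adjusted p = 0.0792, and adjusted p = 0.207 at 48 h). A lower level of ATF4 mRNA could contribute, but it stays open: ATF4 had -0.41 ± 0.10 at 24 h with an adjusted p of 0.240, so a fall of ATF4 mRNA and no change cannot be told apart by this test. With the GC trend removed ATF4 did not pass by edgeR at 24 h or 48 h either. In that fit 23 of the 34 members fell and 3 rose at 24 h, 26 fell and 3 rose at 48 h, and ATF4 rose between the DMSO times. Not passing does not show that ATF4 mRNA was unchanged.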
